A study of Brassica napus with 22 samples.

How the data were processed

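Seeds of Brassica napus cultivar Topas, grown under long days, were collected by the authors at the globular stage. Laser microdissection, read from an abbreviation in the name of the deposited table, gave 7 compartments, and whole seeds were taken beside them. Per the labels, total RNA of all samples was extracted with an Ambion reagent and a NuGen Ultralow kit was used. The labels name Trimmomatic 0.36, HISAT2 and Cufflinks, without roles, settings or genome build. The unit is a score: FPKM (fragments scaled to transcript length and to the number of mapped fragments) that the authors rounded to whole numbers and deposited as 1 value per group, from 2 to 4 libraries in each. How the libraries were combined is not stated. The heading of the whole seed column names no unit and was taken as FPKM from its values. The other column used, of other unit, is the deposited gene length in bases. All values checked were whole numbers (100%). Low values are therefore coarse. A further 1 column of FPKM, headed gCZSC, matched no sample in the labels and was not used.

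The table held 101040 genes, of which 593 had no values for the compartments and were left out of all comparisons. Of the remaining 100447, 54278 genes with at least 1 FPKM in at least 2 of the 8 columns were compared. Gene names of the form BnaA01g00010D carry the chromosome and the subgenome letter, and positions are those of the deposited table, with starts moved by 1: the deposited length equals end minus start for 17707 genes and exceeds it by 1 for 0 genes, as with a start counted from 0. The authors' best Arabidopsis protein match linked 51801 of the compared genes to an Arabidopsis locus, and gene symbols in the text are those of that locus, so that several copies share a symbol.

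For each of 15 comparisons fixed before the data were examined, the difference was the mean of log2(FPKM + 1) over the columns of 1 side minus that over the other side. The comparisons were filial against maternal compartments, each compartment against the other 6, 6 pairs of compartments, and whole seed against the 7 compartments. The whole seed, which holds all tissues, was left out of the filial and maternal sides. The plan called for moderated tests of replicate libraries with limma, set tests with camera, a permutation test of subgenome shares and the omission of each replicate in turn. With 1 column per group none of these could be run. In their place a gene was counted as higher or lower when its difference was at least 1 log2 unit (2-fold) and the mean of the higher side at least 5 FPKM. This is a rule of size and not a test, and it carries no error rate. In simulated data for the embryo proper, with noise set at 0.3 log2 (SD), the code found 100 of 100 genes planted at 4-fold and 100 of 100 at 8-fold, and counted 0.0518% of unchanged genes. The noise was assumed and is small beside the planted folds, so this checks the code and not the power on the deposited values.

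Lists of Arabidopsis genes, 15 in number with 245 loci, were fixed before the data were examined: embryo development, endosperm development, chalazal endosperm, flavonoid and proanthocyanidin, mucilage and seed coat epidermis, sugar and amino acid transport, vascular tissue, cell cycle, photosynthesis, seed reserves, hormone metabolism, DNA methylation and Polycomb, programmed cell death, heat and wound stress, and housekeeping. For each list the text gives copies higher, lower and neither, and the median difference was placed among 10000 random lists matched on 20 bins of mean expression, as a description. Gene descriptions enriched among genes at least 2-fold above each other compartment were found against 1000 random sets drawn from 41502 genes at 5 FPKM or more in a compartment, matched on expression.

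Named genes followed a rule fixed before the data were examined: up to 4 copies per list and comparison with the largest difference past the rule of size, the 5 highest and, except for single compartments, the 5 lowest differences among described genes whose sides do not overlap, and the 3 most abundant genes of each column. Homeolog pairs were Arabidopsis loci with exactly 1 A and 1 C copy compared, and are putative. Folds are not given against a group listed at 0.

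Alternatives set before the data were examined, as far as they could be run, were a pseudocount of 0.1, no filter on low values, a filter of 5 FPKM in 2 columns, quantile normalisation, scaling of columns to a common median of genes at 1 FPKM or more, a detection threshold of 5, and subgenome shares without the 100 genes of highest mean value or over detected genes. A detection threshold of 0.1 equals that of 1 in whole numbers. Added after the data were seen were the rule without the floor of 5 FPKM, rescaling of columns to a common sum without rRNA and organelle genes, omission of the micropylar endosperm column, and the lists under these scalings. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.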

Results

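Oilseed rape (Brassica napus) cultivar Topas was sampled at the globular stage of embryo development, when the embryo is a small ball of cells and the endosperm fills most of the seed. Laser microdissection, which frees chosen cells from a tissue section under a microscope, gave RNA from 7 compartments. Filial tissue, formed by fertilisation, comprised 4 of them: the embryo proper and the micropylar, peripheral and chalazal endosperm. Maternal tissue comprised 3: the chalazal proliferating tissue, the inner seed coat and the outer seed coat. Intact whole seeds were profiled beside them. The sample labels list 22 libraries, 2 for the embryo proper, 4 for the micropylar endosperm, 2 for the peripheral endosperm, 3 for the chalazal endosperm, 3 for the chalazal proliferating tissue, 3 for the inner seed coat, 2 for the outer seed coat and 3 for the whole seed. The deposited table holds 1 combined column per group, so no spread between replicates could be computed and every difference is given without a test. Read depth is not stated, and no error or interval could be attached to any value.

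Compartments differed in how concentrated their transcriptomes were. Genes under 300 bases held 22.2% of all FPKM in the chalazal endosperm and 18.5% in the micropylar endosperm, against 9.20% in the peripheral endosperm and 4.35% in the inner seed coat. The 10 most abundant genes held 37.1% of the FPKM in the micropylar endosperm, 25.6% in the embryo proper, 17.1% in the chalazal endosperm, 16.9% in the inner seed coat, 14.0% in the peripheral endosperm, 13.6% in the chalazal proliferating tissue and 10.9% in the outer seed coat. In the whole seed they held 4.18%. Genes of ribosomal RNA and of the organelles, 194 in the table, took 36.9% of the FPKM in the micropylar endosperm, 16.0% in the embryo proper and 11.1% in the peripheral endosperm. Their share was 4.17% in the chalazal endosperm, 4.88% in the chalazal proliferating tissue, 8.21% in the inner seed coat, 7.27% in the outer seed coat and 0.0355% in the whole seed. Column sums of FPKM ran from 655846 in the whole seed to 2283005 in the chalazal endosperm.

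At 1 FPKM or more, 66732 genes were detected in at least 1 compartment, 16511 in all 7 and 14533 in exactly 1. The inner seed coat had 46954 detected genes, the peripheral endosperm 42784, the chalazal proliferating tissue 42514, the outer seed coat 41092, the chalazal endosperm 35892, the embryo proper 34368 and the micropylar endosperm 30527. The whole seed had 44707. This order depends on the threshold: at 5 FPKM the embryo proper, with 22632, passed the peripheral endosperm, with 21194, and the chalazal endosperm was lowest, with 19924 against 20803 in the micropylar endosperm. In the whole seed, 7930 genes that reached 5 FPKM in a compartment were listed at 0, among them 1776 that were highest in the micropylar endosperm, 1698 in the chalazal endosperm and 1576 in the embryo proper. The reverse, 5 FPKM or more in the whole seed and 0 in all 7 compartments, held for 135 genes.

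Across genes, the peripheral and chalazal endosperm resembled each other most, with a Pearson correlation of log2(FPKM + 1) of 0.81. Inner and outer seed coat correlated at 0.79, and chalazal proliferating tissue and inner seed coat at 0.77. Micropylar endosperm was at 0.49 with the peripheral and 0.44 with the chalazal endosperm. It was no closer than 0.52 to any compartment, with the outer and inner seed coat nearest. Noise in a column lowers its correlations, so these values do not tell a distinct region from a noisy column. The whole seed was closest to the outer seed coat at 0.77 and to the inner seed coat at 0.75, and farthest from the chalazal endosperm at 0.38. These correlations run across genes, which are not independent replicates, and all pairs of the 8 columns were compared.

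**Figure D1:**
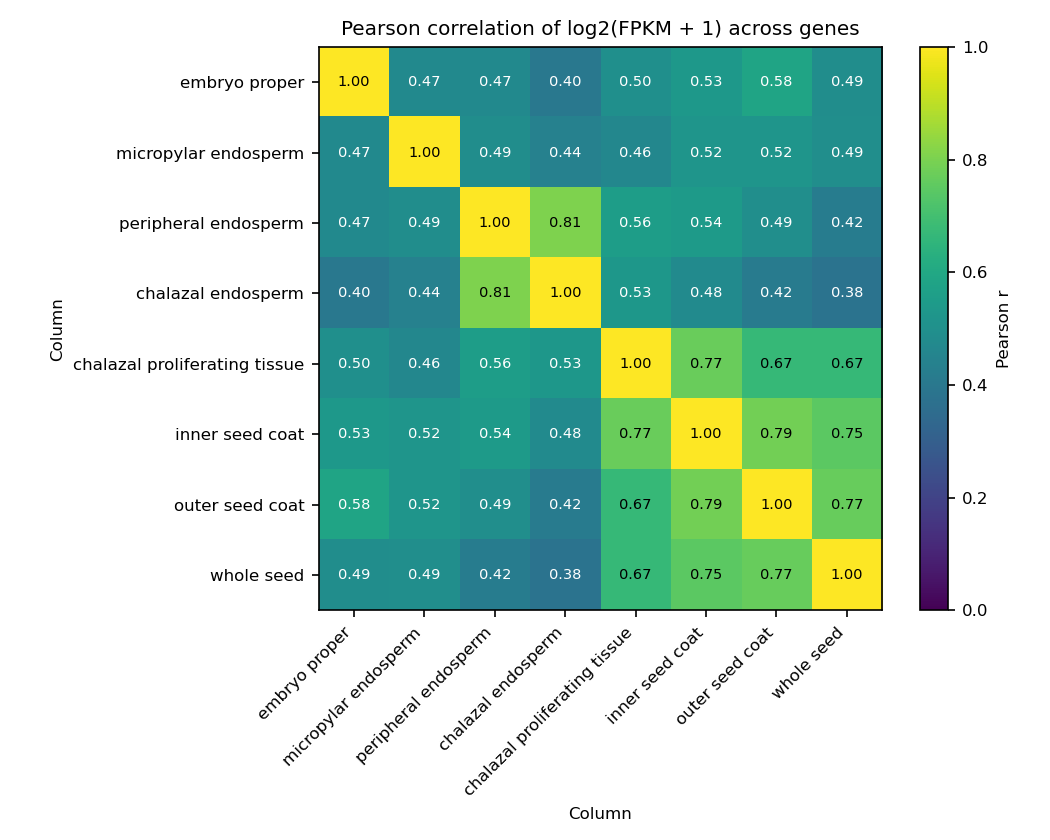
Pearson correlation of log2(FPKM + 1) across genes for each pair of the 8 columns (both axes; colour and printed value give r). Peripheral and chalazal endosperm form 1 bright pair at 0.81, and the 3 maternal compartments and the whole seed form another block, with values between 0.67 and 0.79.

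Filial and maternal compartments were compared to ask which programmes follow the products of fertilisation and which follow the mother plant. Regulators of embryo and endosperm that passed the rule of size were mostly higher on the filial side. The LEC1 copy BnaA07g10770D (chromosome A07, 10129311 to 10131376), a master regulator of embryo identity, reached 164 FPKM in the embryo proper and 0 in each maternal compartment. The AGL62 copy BnaA10g13240D, a repressor of endosperm cellularisation, reached 227 in the peripheral and 445 in the chalazal endosperm against at most 2 in maternal tissue. It was listed at 0 in the micropylar endosperm. Among transparent testa and cell death genes, those past the rule of size were higher on the maternal side. The outer seed coat did not share in the cell death genes, with 0 higher, 3 lower and 14 neither against the other 6 compartments. The TT16 copy BnaA03g39500D, a MADS-box regulator of the inner seed coat, reached 579 FPKM in the chalazal proliferating tissue and 322 in the inner seed coat against at most 5 in filial tissue. An alpha-L-arabinofuranosidase gene, BnaA10g25450D, had the lowest difference, with 2404, 2299 and 1743 FPKM in the 3 maternal compartments and 0 in the micropylar and peripheral endosperm. At the other end stood a proline-rich protein gene, BnaA06g16030D, with 9930 FPKM in the chalazal and 2611 in the micropylar endosperm against 12, 0 and 0 in maternal tissue.

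By list, the filial side was at least 2-fold higher for 47 copies of endosperm regulators, lower for 1 and neither for 29. Embryo regulators gave 18 higher, 1 lower and 32 neither, chalazal endosperm markers 8, 0 and 8, and seed reserve genes 33, 1 and 14. Photosynthesis genes gave 54 higher, 2 lower and 27 neither; the RBCS3B copy BnaA02g12800D, a Rubisco small subunit, had 2348 FPKM in the peripheral endosperm and at most 34 in maternal tissue. Cell cycle genes gave 25 higher, 2 lower and 68 neither, and DNA methylation and Polycomb genes 14, 7 and 22. Flavonoid genes gave 0 higher, 27 lower and 38 neither, mucilage and seed coat epidermis genes 1, 26 and 45, heat and wound genes 1, 15 and 27, and programmed cell death genes 0, 8 and 9. Sugar and amino acid transporters were split at 10 higher, 8 lower and 26 neither, and their median of 0.03 turned to -0.13 with columns scaled to a common median and to -0.33, with 4 higher and 9 lower, without the micropylar endosperm. Vascular markers gave 4 higher, 0 lower and 6 neither, which became 0 and 0 without the micropylar endosperm. Hormone metabolism genes gave 3 higher, 0 lower and 12 neither, with a median of -0.27 that became 0.12 under quantile normalisation. Housekeeping genes gave 2, 5 and 37, with a median of -0.01.

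In total, 5494 genes were at least 2-fold higher and 9147 at least 2-fold lower on the filial side. With columns scaled to a common median the split was 3835 and 12382 and the median of all genes moved by -0.25 log2, and with columns rescaled to a common sum without rRNA and organelle genes it was 4087 and 12526, with a shift of -0.25.

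**Figure D2:**
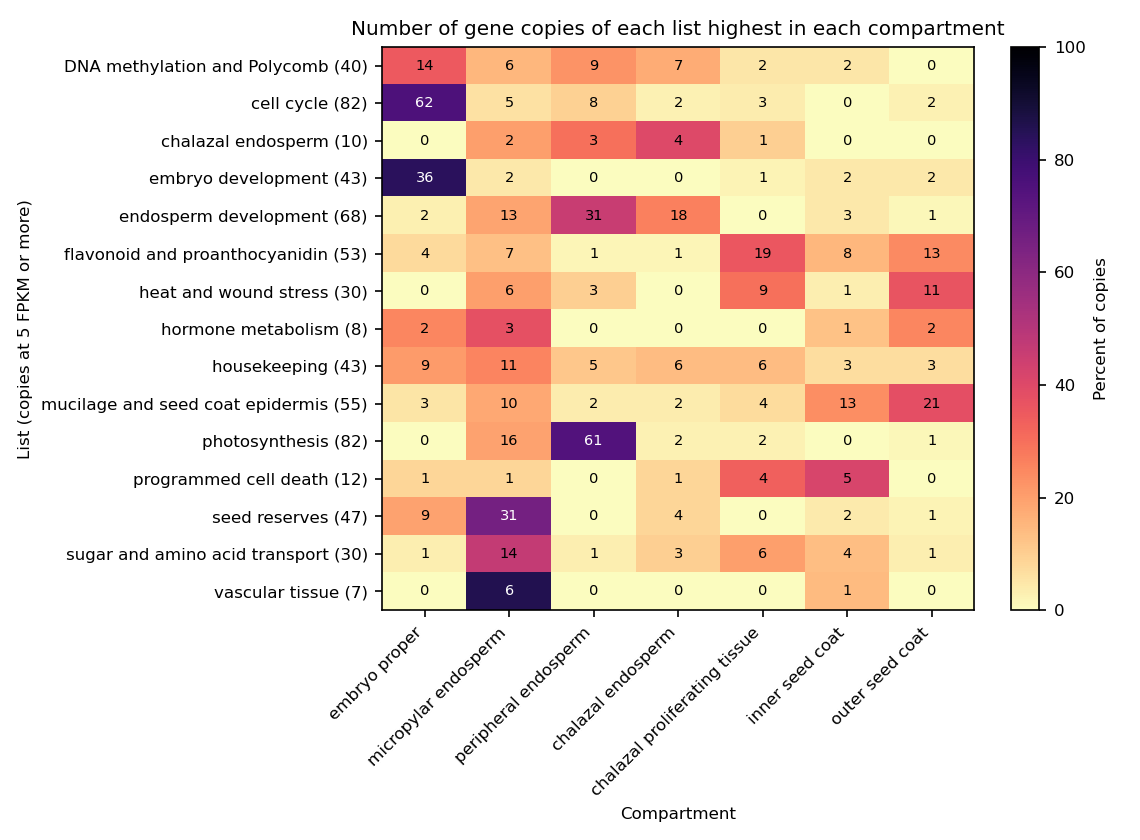
Number of gene copies of each list (y axis, with the copies that reach 5 FPKM in a compartment in brackets) that are highest in each compartment (x axis); colour gives the percent of copies. Of 43 embryo copies, 36 were highest in the embryo proper, of 82 photosynthesis copies 61 in the peripheral endosperm, and of 47 reserve copies 31 in the micropylar endosperm.

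The embryo proper was set against the other 6 compartments to find transcripts enriched in the embryo. Embryo regulators led: 39 copies were at least 2-fold higher, 0 lower and 12 neither, with a median difference of 3.69 log2. LEC1 was represented by BnaA07g10770D and by BnaC07g14150D at 95 FPKM, the ABI3 copy BnaA03g37510D, a seed maturation factor, had 50 FPKM against at most 1 elsewhere in the compartments, and the MP copy BnaC07g48490D, an auxin response factor, had 46. Cell division genes followed, with 71 copies higher, 0 lower and 24 neither. CYCB2;2 (BnaAnng23850D), a mitotic cyclin, had 72 FPKM against 11 in the outer seed coat, and the cytokinesis syntaxin KNOLLE (BnaA06g04950D) had 72 against 13. DDM1, a chromatin remodeler needed for DNA methylation, had 4 copies among those named, from 27 FPKM in BnaA09g52610D to 58 in BnaA07g37430D, in a list with 16 higher, 8 lower and 19 neither. The median of that list, 0.55, lay inside the central 95% of random lists, at percentile 95.4. WRI1, a regulator of oil synthesis, was at 43 FPKM in BnaA07g16350D, and seed reserve genes gave 22 higher, 7 lower and 19 neither.

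Photosynthesis genes were lower in the embryo proper, 63 copies against 0 higher and 20 neither. The LHCA1 copy BnaA07g16530D, an antenna protein, was listed at 0 there and at 229 in the peripheral endosperm. Endosperm regulators gave 3 higher, 42 lower and 32 neither, and heat and wound genes 0, 14 and 29. The largest differences were a copy annotated as translation initiation factor 3G1, BnaC09g49390D, at 4253 FPKM against at most 39, and a pair of glycine-rich protein genes, BnaC03g43520D at 886 and BnaA03g37230D at 1423. At least 2-fold above each other compartment stood 3925 genes, in which pentatricopeptide repeat proteins numbered 38 against at most 23 in 1000 matched random sets and kinesin-type motor proteins 16 against at most 13. Here and below, descriptions were kept only if they exceeded every random set, so these counts are not a test. In total 10891 genes were higher and 9344 lower, a split that became 6905 and 11129 with columns scaled to a common median, with a shift of -0.12; the common sum moved the median of all genes by 0.17.

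The micropylar endosperm surrounds the embryo, and its profile combined storage, transport and vascular genes. Seed reserve genes gave 36 copies higher, 3 lower and 9 neither, with a median of 3.98 log2. The SESA4 copy BnaA03g06940D (A03, 3072742 to 3073302), a 2S albumin storage protein, had 298 FPKM there, 26 in the chalazal endosperm and 10 in the embryo proper, and the cruciferin copy CRU3 BnaA01g08350D had 203, 24 and 0. Sugar and amino acid transporters gave 18 higher, 3 lower and 23 neither: the sugar exporter SWEET15 (BnaA02g01450D) had 161 FPKM against at most 4, and UMAMIT18 (BnaAnng37680D), an amino acid exporter, had 83 and was listed at 0 in the other compartments. The phloem lectin PP2-A1 had 106 FPKM in BnaA01g34970D and 90 in BnaA08g09350D, each against at most 1, in a vascular list with 6 higher, 0 lower and 4 neither.

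Among the endosperm regulators, the WRKY factor MINI3 stood out with 360 FPKM in BnaAnng25430D and 225 in BnaC03g77690D, in a list with 21 copies higher, 30 lower and 26 neither. Photosynthesis genes gave 64 higher, 4 lower and 15 neither, and cell cycle genes 10, 28 and 57. Embryo regulators gave 12 higher, 4 lower and 35 neither, with a median of -0.37 that became 0.15 under quantile normalisation. Heat and wound genes gave 11 higher, 5 lower and 27 neither with a median of 0.01, and 7 and 7 with a median of -0.19 once columns were scaled to a common median. The 3720 genes at least 2-fold above each other compartment held 8 late embryogenesis abundant proteins against at most 5 in matched random sets and 12 cupin family proteins against at most 10. Abundant seed coat transcripts were also seen in this column: 11 genes at 1000 FPKM or more in the outer seed coat and 10-fold above the embryo proper, the peripheral and chalazal endosperm and the chalazal proliferating tissue had a median of 12.3% of their outer seed coat level here. For 19 such genes of the inner seed coat the median was 2.80%. In total 10557 genes were higher and 9880 lower, and 5744 and 13251 with a common median, where the median of all genes moved by -0.23.

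The peripheral endosperm lines the seed cavity. Photosynthesis genes led by number of copies: 78 were higher, 1 lower and 4 neither, with RBCS1A at 1608 FPKM in BnaC02g17140D and RBCS3B at 2348 in BnaA02g12800D (A02, 6921010 to 6923164) against 386 in the next compartment, the micropylar endosperm. Of 82 copies, 61 were highest here, 49 with columns rescaled to a common sum and 71 with a common median. Endosperm regulators gave 48 higher, 1 lower and 28 neither. The AGL62 copy BnaA02g06300D had 181 FPKM against 6 in the chalazal endosperm, and the MINI3 copy BnaA08g29320D had 99 against 0 there. TFL1 (BnaA10g26300D), a mobile regulator of endosperm cellularisation, had 43 FPKM and the cytokinin oxidase CKX2 (BnaA09g52930D) had 104. The chromomethylase CMT3 (BnaC03g49350D) had 42 FPKM against at most 2, and DNA methylation genes gave 13 higher, 11 lower and 19 neither.

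Of the 5 genes with the largest difference for the peripheral endosperm, 4 encode defensin-like or low-molecular-weight cysteine-rich peptides. A defensin-like gene, BnaC02g01190D (C02, 501848 to 502424), had 4127 FPKM against at most 48, and 17 genes described as DEFL family, without the low-molecular-weight cysteine-rich ones, were at least 2-fold above each other compartment against at most 10 in matched random sets. Proteins of the S1 self-incompatibility family numbered 22 against at most 11. Cell cycle genes gave 23 higher, 7 lower and 65 neither. Seed reserve genes gave 1 higher, 9 lower and 38 neither, but 3 higher and 1 lower without the micropylar endosperm. In total 7423 genes were higher and 6205 lower, and 5900 and 7894 with the common sum, where the median of all genes moved by -0.16; the common median moved it by 0.22.

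The chalazal endosperm lies against the vascular supply of the seed. Among its genes of largest difference were single members of the RALF-like peptide and lipid transfer protein families: BnaAnng10580D (Ann random, 11483755 to 11484006), a RALF-like 28 homolog, had 44016 FPKM against 395 in the peripheral endosperm, BnaC05g47090D, a RALF-like 21 homolog, had 40366 against 216, and the lipid transfer protein gene BnaA06g04240D had 25527 against 247. Endosperm regulators gave 37 higher, 5 lower and 35 neither, with the MADS-box gene AGL35 at 1107 FPKM in BnaA02g31510D and the AGL62 copy BnaC04g15630D at 350. Cytokinin synthesis was marked by IPT8, at 273 FPKM in BnaC01g33530D and 58 in BnaA01g26240D against at most 4 elsewhere. Chalazal endosperm markers gave 5 higher, 0 lower and 11 neither, and their median of 0.20 became -0.23, with 4 higher and 0 lower, under the common sum. The peripheral endosperm gave the same counts for this list, with a median of 0.61, and between these regions 4 copies were higher and 4 lower in the chalazal endosperm. VRN2, a Polycomb gene, reached 86 FPKM in BnaA01g18110D.

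Cell cycle genes were lower in the chalazal endosperm, 36 copies against 4 higher and 55 neither, and so were mucilage genes, 28 against 2 and 42. The replication helicase gene MCM3 (BnaCnng57480D) was at 2 FPKM here and at 62 in the embryo proper. Seed reserve genes gave 21 higher, 3 lower and 24 neither. Photosynthesis genes gave 21 higher, 7 lower and 55 neither, which turned to 8 higher and 28 lower under the common sum, and DNA methylation and Polycomb genes gave 13, 11 and 19, which turned to 6 higher and 16 lower. Of the 2064 genes at least 2-fold above each other compartment, 23 were described as DEFL family against at most 17 in matched random sets, 25 were F-box proteins with an interaction domain against at most 12, and 16 were C2H2-like zinc fingers against at most 10. In total 7362 genes were higher and 8395 lower, and 2889 and 16073 with the common sum, where the median of all genes moved by -0.46.

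**Figure D3:**
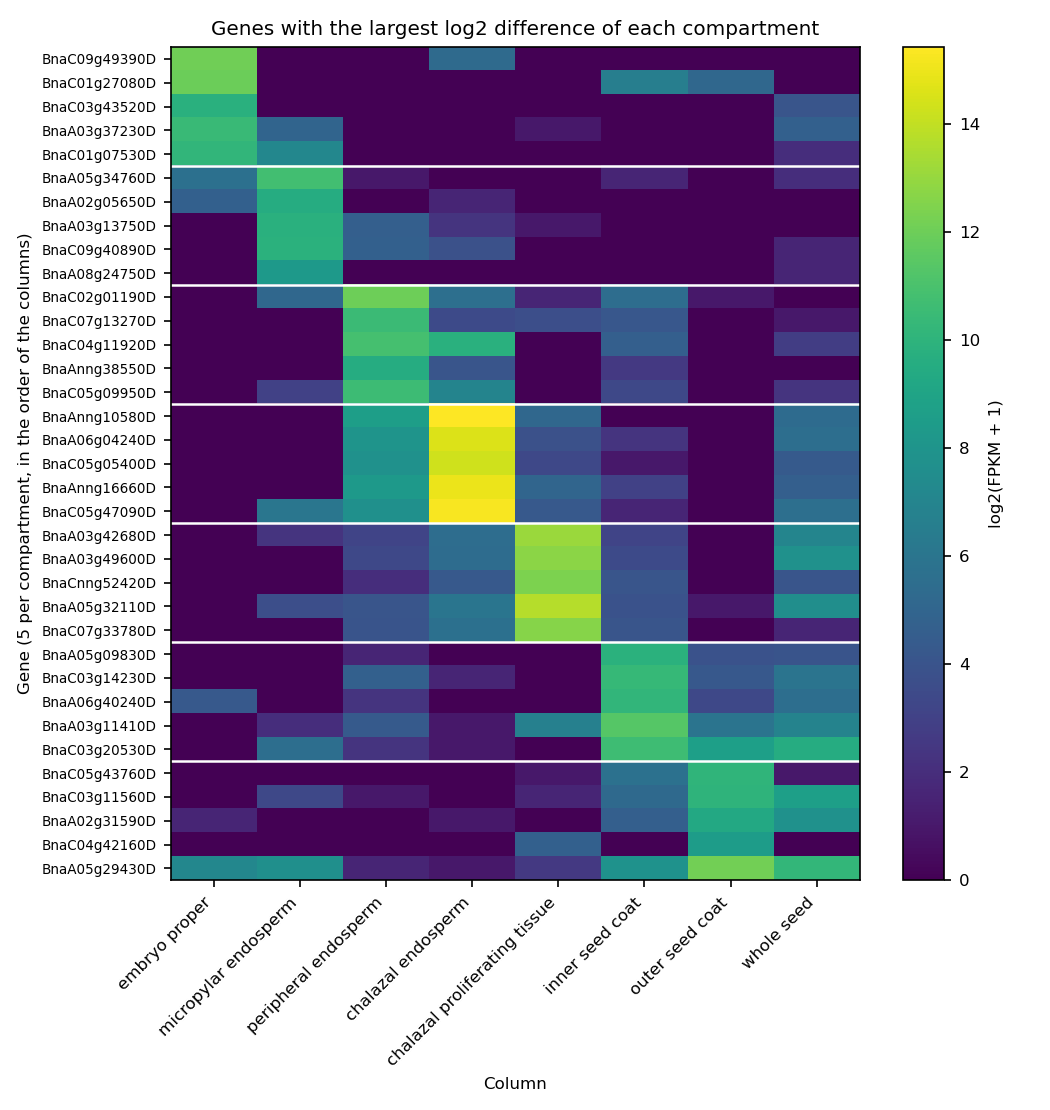
Expression as log2(FPKM + 1), in colour, of the 5 genes with the largest log2 difference of each compartment against the other 6 (y axis, white lines between compartments) in the 8 columns (x axis). The chalazal endosperm block is the brightest, up to 44016 FPKM in BnaAnng10580D, and its 5 genes are at 49 FPKM or less in the whole seed.

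The chalazal proliferating tissue is the maternal tissue next to the chalazal endosperm. Flavonoid genes gave 31 copies higher, 2 lower and 32 neither, led by TT16 at 579 FPKM in BnaA03g39500D (A03, 19707065 to 19709464) and 618 in BnaC02g42240D. Programmed cell death genes gave 9 higher, 0 lower and 8 neither: the cysteine endopeptidase CEP1 had 465 FPKM in BnaA03g23380D and 237 in BnaC03g27700D, and the nuclease BFN1 (BnaCnng63000D) had 24. The amino acid exporter UMAMIT28 (BnaC08g49790D) had 112 FPKM against 2 in the embryo proper and 0 in the rest. Heat and wound genes gave 11 higher, 3 lower and 29 neither although their median was -0.32, with the zinc finger gene ZAT10 (BnaA09g27780D) at 120 FPKM. The largest differences belonged to an HSP20-like chaperone, BnaA03g42680D (A03, 21403472 to 21405133), at 8696 FPKM against at most 45, and a kelch repeat protein, BnaA05g32110D, at 13251 against at most 62.

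Among the 2232 genes at least 2-fold above each other compartment, kelch repeat proteins numbered 23 against at most 15 in matched random sets, SAUR-like auxin response proteins 12 against at most 8, HSP20-like chaperones 11 against at most 10 and Dof-type zinc fingers 7 against at most 4. Seed reserve genes gave 0 higher, 30 lower and 18 neither, and endosperm regulators 1, 44 and 32. Cell cycle genes gave 18 higher, 26 lower and 51 neither, and 22 of each with columns scaled to a common median. In total 8930 genes were higher and 6100 lower; the median of all genes moved by 0.21 with the common median and by -0.13 with the common sum.

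The inner seed coat was set against the other 6 compartments. Besides a gene without a description, its most abundant transcripts encode a Kunitz-type protease inhibitor, BnaA07g30010D, at 19085 FPKM, and the delta vacuolar processing enzyme DVPE, a caspase-like protease of inner integument cell death. DVPE copies had 19004 FPKM in BnaA05g18870D (A05, 14274447 to 14276941) and 18024 in BnaC05g31880D, against 1795 and 563 in the chalazal proliferating tissue, and CEP1 (BnaA03g23380D) had 837. Programmed cell death genes gave 7 higher, 0 lower and 10 neither. Mucilage and seed coat genes gave 23 higher, 1 lower and 48 neither, with MYB61 at 182 FPKM in BnaA09g48440D. Flavonoid genes gave 17 higher, 1 lower and 47 neither, with the glutathione transferase TT19 (BnaA10g17440D) at 66 FPKM against 5 in the outer seed coat.

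Cell cycle and photosynthesis genes were low in the inner seed coat: 43 copies lower, 0 higher and 52 neither for the first, and 71 lower, 0 higher and 12 neither for the second. The LHCA4 copy BnaCnng15190D was at 9 FPKM against 433 in the micropylar endosperm. A homolog of the senescence protease SAG12, BnaA06g40240D, had 1116 FPKM against at most 19. In total 8363 genes were higher and 3792 lower; the median of all genes moved by -0.24 under quantile normalisation, 0.21 with the common median and 0.24 with the common sum.

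The outer seed coat forms the mucilage cells of the epidermis. Mucilage and seed coat epidermis genes gave 34 higher, 1 lower and 37 neither: the homeodomain regulator GL2 (BnaC06g18950D; C06, 21307997 to 21312337) had 35 FPKM against 1 in the inner seed coat and 0 in the other compartments, and the cellulose-organising COBL2 (BnaAnng33230D) had 114 against 60. TTG2 (BnaC03g20650D), a WRKY regulator of mucilage and tannin, had 48 FPKM against at most 2. Heat and wound genes gave 19 higher, 1 lower and 23 neither, with the jasmonate synthesis gene LOX2 at 168 FPKM in BnaCnng78230D and 156 in BnaC06g26190D. Cell cycle genes gave 19 higher, 3 lower and 73 neither. Flavonoid genes gave 18 higher, 9 lower and 38 neither with a median of -0.33; TT7 (BnaA10g23330D), a flavonoid hydroxylase, had 117 FPKM against at most 30.

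Lipid transfer protein 6 (BnaC05g43760D) had 1108 FPKM in the outer seed coat against 54 in the inner seed coat. MADS K-box proteins numbered 13 among the 1590 genes at least 2-fold above each other compartment, against at most 7 in matched random sets, and AP2/ERF-type factors 14 against at most 9. Photosynthesis genes gave 9 higher, 21 lower and 53 neither, which turned to 20 higher and 13 lower under the common sum and to 13 and 12 without the micropylar endosperm. In total 8013 genes were higher and 5643 lower, and 13386 and 3583 with the common sum, where the median of all genes moved by 0.54; the common median moved it by 0.23.

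Chalazal against peripheral endosperm compared regions of 1 tissue. Division and photosynthesis genes were lower in the chalazal region, with 36 cell cycle copies lower, 3 higher and 56 neither, and 68 photosynthesis copies lower, 1 higher and 14 neither. The cyclin copy BnaC03g02420D (CYCB1;2) was at 42 FPKM in the peripheral and 0 in the chalazal endosperm. Seed reserve genes were higher in the chalazal region, 25 against 2 lower and 21 neither; the SESA1 copy BnaA01g16180D was at 19 against 0. Endosperm regulators parted by copy, 12 higher, 28 lower and 37 neither, with AGL35 (BnaC02g40080D) at 314 against 2 and MINI3 (BnaC03g70660D) at 0 against 74. A gene of the maternally expressed gene family, BnaA02g13580D, had 794 FPKM against 0, and a defensin-like gene, BnaAnng06170D, had 3 against 755. In total 4655 genes were higher and 6193 lower, and 3265 and 7310 with the common median (shift of -0.11) and 1705 and 9496 with the common sum (shift of -0.42).

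Chalazal against micropylar endosperm placed endosperm regulators on the chalazal side. Endosperm regulators gave 33 higher, 13 lower and 31 neither, with AGL62 (BnaA10g13240D) at 445 FPKM against 0 and AGL35 (BnaC07g28640D) at 440 against 0. Seed reserve genes gave 4 higher, 34 lower and 10 neither, transporters 4, 17 and 23, vascular markers 0, 6 and 4, and embryo regulators 0, 12 and 39. SWEET15 (BnaA02g01450D) was at 0 against 161 and the oleosin copy BnaC07g39370D (OLEO1), an oil body protein, at 2 against 77. Lipid transfer protein 1 (BnaC04g45800D) was at 2 against 3587. In total 9915 genes were higher and 11291 lower, and 11082 and 6949 with the common median but 4485 and 15230 with the common sum.

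Micropylar against peripheral endosperm parted storage genes from endosperm regulators in the same way. Seed reserve genes gave 38 higher, 4 lower and 6 neither, and transporters 17, 4 and 23; SUC1 (BnaA07g29680D), a sucrose carrier, was at 54 against 0. Endosperm regulators gave 11 higher, 44 lower and 22 neither, with AGL62 (BnaCnng38710D) at 0 against 218. Photosynthesis genes gave 6 higher, 36 lower and 41 neither, with PSBP1 (BnaC08g44890D) at 0 against 257. A defensin-like gene, BnaC06g12820D (C06, 15546292 to 15546783), was at 0 against 4571. In total 10480 genes were higher and 10417 lower, and 5684 and 13963 with the common median, where the median of all genes moved by -0.71.

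Chalazal proliferating tissue against chalazal endosperm set maternal against filial tissue at the same pole. Flavonoid genes gave 33 higher, 2 lower and 30 neither, programmed cell death genes 9, 1 and 7, and mucilage genes 20, 4 and 48. SBT1.7 (BnaAnng14520D), a subtilase of mucilage release, was at 91 FPKM against 0, and the copper transport protein gene BnaC07g20570D was at 4905 against 6. Endosperm regulators gave 1 higher, 39 lower and 37 neither and seed reserve genes 0, 26 and 22. Cell cycle genes gave 25 higher, 8 lower and 62 neither, with MCM7 (BnaC03g31160D) at 28 against 1. The largest negative differences included a glycosyltransferase gene, BnaA02g24050D, at 1 against 9469, and a carbohydrate-binding X8 domain gene, BnaC03g28650D, at 4 against 21512. In total 9662 genes were higher and 7238 lower, and 12406 and 3251 with the common sum (shift of 0.56); the common median moved the median of all genes by 0.14.

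Chalazal proliferating tissue against inner seed coat compared maternal tissues that both express TT16. Photosynthesis genes gave 61 higher, 4 lower and 18 neither in the chalazal proliferating tissue, with LHCB6 (BnaC08g16770D) at 115 against 0, and cell cycle genes gave 23, 0 and 72, with PCNA1 (BnaC08g45280D) at 188 against 16. Flavonoid genes gave 20 higher, 10 lower and 35 neither: the anthocyanidin reductase gene BAN was at 24 against 1 in BnaA01g36200D, and TT2 (BnaA08g29930D), a MYB activator of BAN, was at 2 against 72. Mucilage genes gave 1 higher, 16 lower and 55 neither. Programmed cell death genes gave 5 higher, 4 lower and 8 neither, and 4 and 5 with the common sum. In total 5612 genes were higher and 6476 lower, and 3495 and 8508 with the common sum, where the median of all genes moved by -0.29.

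Inner against outer seed coat placed division and photosynthesis on the outer side, with 38 cell cycle copies lower, 0 higher and 57 neither and 57 photosynthesis copies lower, 3 higher and 23 neither. KNOLLE (BnaC08g13620D) was at 0 against 14 and CDC20.1 (BnaC01g04930D), an activator of the anaphase-promoting complex, at 2 against 40. Programmed cell death genes were higher inside, 7 against 0 lower and 10 neither, with CEP1 (BnaA03g23380D) at 837 against 9. Heat and wound genes gave 1 higher, 15 lower and 27 neither. TT16 marked the inner coat, at 120 against 0 in BnaA09g05410D, while flavonoid genes as a list were split at 17 higher, 15 lower and 33 neither. Mucilage genes were also split, 10, 16 and 46. In total 6346 genes were higher and 4901 lower, and 4538 and 6662 with the common sum.

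The whole seed was set against the mean of the 7 compartments to ask what dissection resolves. The FPKM column that matched no sample is not in this mean. Whether it covers tissue outside the 7 compartments is not known, so a higher whole seed value may reflect tissue not compared here. Flavonoid genes gave 45 higher, 1 lower and 19 neither in the whole seed and mucilage genes 25, 3 and 44; BAN (BnaA03g60670D) had 55 FPKM against 14 in the chalazal proliferating tissue and 0 in the rest. Heat and wound genes gave 29 higher, 1 lower and 13 neither, with the stress zinc finger ZAT12 at 336 FPKM in BnaA03g09250D against at most 27. SWEET10 (BnaA07g09540D; A07, 9291632 to 9293087), a sugar exporter, had 222 FPKM against at most 3, and the cell wall invertase CWINV4 (BnaAnng07590D) had 92 against at most 1. Both loci belong to the chalazal endosperm list, yet these copies were nearly absent from the chalazal endosperm column. That list gave 5 higher, 4 lower and 7 neither in the whole seed, with a median of -0.68. Without the micropylar endosperm it gave 5 higher and 7 lower. Endosperm regulators gave 0 higher, 33 lower and 44 neither, with MINI3 (BnaAnng25430D) listed at 0. DNA methylation and Polycomb genes gave 4, 13 and 26. Chloroplast ribosomal RNA (BnaC09g30110D) was listed at 0 in the whole seed and at 1903 to 172243 FPKM in the compartments.

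Compartment-specific transcripts left unequal traces in the whole seed. Genes at least 10-fold above each other compartment had a median whole seed level of 29.9% of their own compartment's for the outer seed coat (162 genes), 11.4% for the inner seed coat (135 genes), 4.17% for the chalazal proliferating tissue (291 genes), 2.90% for the embryo proper (267 genes), 1.67% for the micropylar endosperm (468 genes), 0.0326% for the chalazal endosperm (602 genes) and 0% for the peripheral endosperm (167 genes). Of these genes, 291 of the chalazal and 110 of the peripheral endosperm were listed at 0 in the whole seed. All were picked as extreme in their own column, so noise in that column lowers the percent. The whole seed column may also have been made differently, so the percents do not measure the share of a tissue in the seed. In total 8724 genes were higher in the whole seed and 5210 lower, and 14750 and 3164 with the common sum (shift of 0.53). The common median moved the median of all genes by 0.18.

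**Figure D4:**
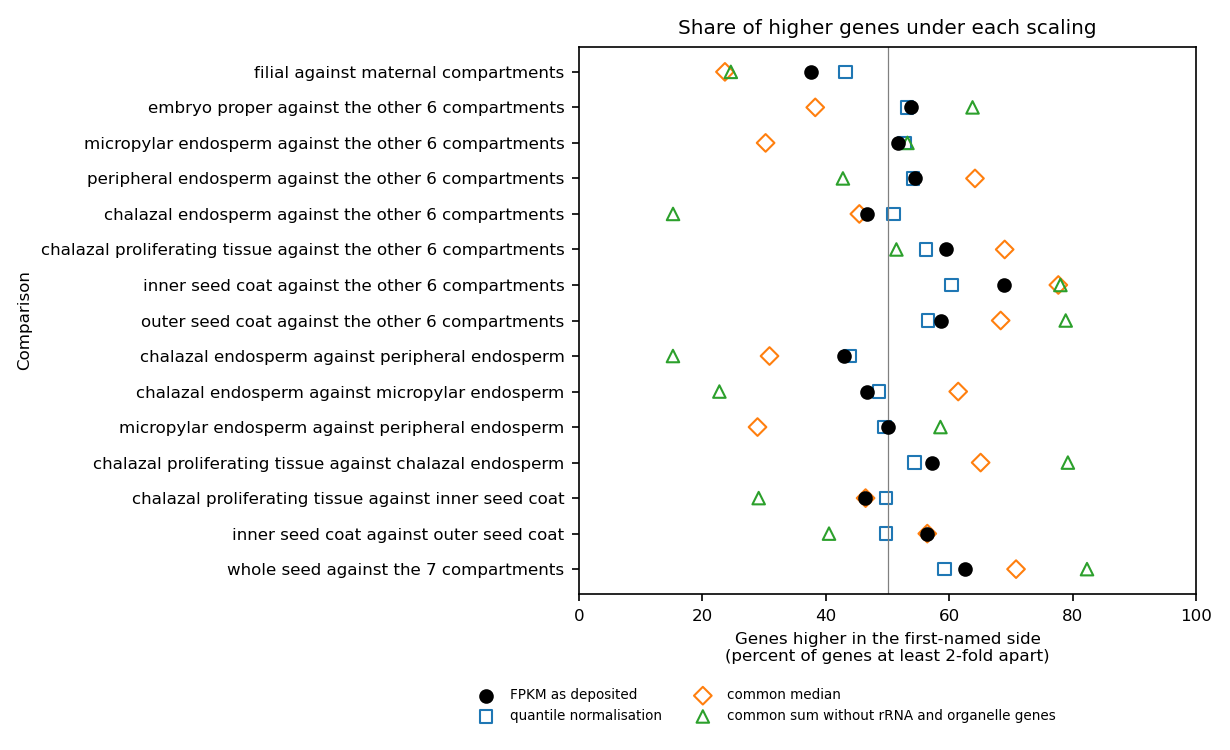
Share of genes higher in the first-named side among those at least 2-fold apart (x axis, percent) for each of the 15 comparisons (y axis), with FPKM as deposited (black) and under the 3 scalings (open symbols). The chalazal endosperm against the other 6 moves farthest, from 46.7% as deposited to 15.2% with the common sum.

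Oilseed rape carries the A and C subgenomes, and each gene's name gives its subgenome. The A subgenome held 50.6% of A plus C FPKM in the whole seed, 49.1% in the inner seed coat, 48.3% in the chalazal proliferating tissue, 47.2% in the outer seed coat, 46.3% in the chalazal endosperm, 43.9% in the peripheral endosperm, 41.6% in the embryo proper and 35.8% in the micropylar endosperm. Without the 100 genes of highest mean value these shares drew together, from 47.0% in the chalazal proliferating tissue to 49.9% in the chalazal endosperm. The shares count genes of rRNA and organelles by their gene names. Such genes took 36.9% of the FPKM in the micropylar endosperm and 0.0355% in the whole seed. Putative homeologs, 6371 pairs of an A and a C copy with the same Arabidopsis best hit and no other copy compared, mostly pointed the same way where both copies differed at least 2-fold: 98.2% of such pairs for the inner seed coat, 97.2% for the peripheral endosperm, 97.1% for the chalazal proliferating tissue, 95.3% for the chalazal endosperm, 91.6% for the outer seed coat, 90.2% for the embryo proper and 69.1% for the micropylar endosperm. How reads that match both copies were assigned is not stated, and shared reads would raise this agreement. Among the 3073 pairs with a copy at 5 FPKM or more in the peripheral endosperm, the C copy was at least 2-fold above the A copy in 24.5% and the A copy above the C copy in 17.8%. Among 3429 such pairs in the micropylar endosperm these were 39.6% and 36.7%.

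**Figure D5:**
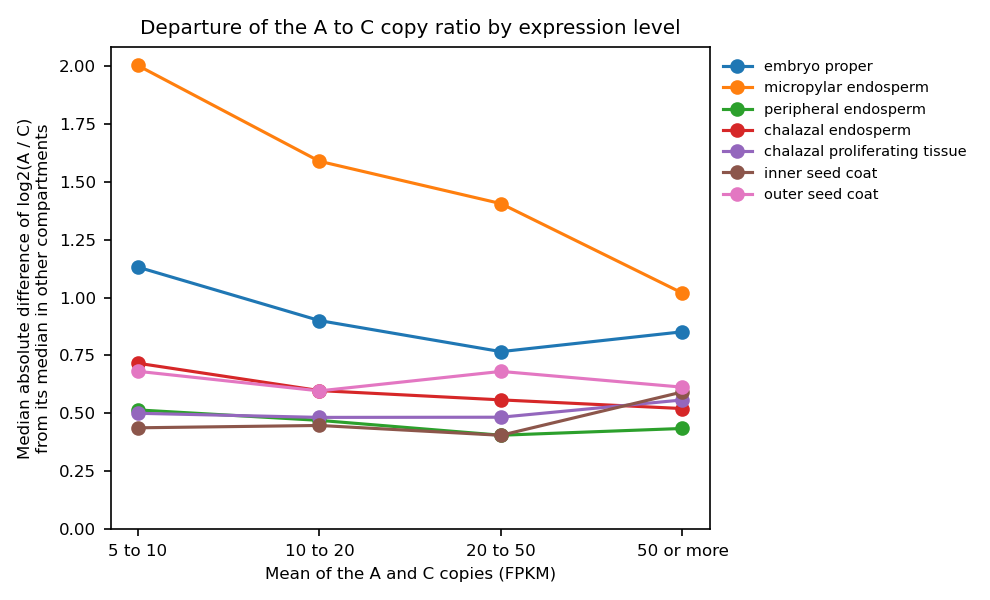
Median absolute difference of the log2 ratio of A to C copy from its median in the other compartments (y axis) by the mean level of the pair in FPKM (x axis), a line per compartment. The micropylar endosperm lies highest, from 2.0 at 5 to 10 FPKM to 1.02 at 50 FPKM or more, and the inner seed coat starts lowest at 0.44.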

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

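Nothing in this part was tested. The whole seed column held values for genes that the table lists without any compartment value. Of these genes, 274 were at 1 FPKM or more and 137 at 5 FPKM or more in the whole seed, and they stood out as signal in genes that no comparison uses. The highest, BnaAnng18430D, had 306 FPKM; it was chosen after its values were seen.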

How the results depend on the processing

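The alternatives without a floor of 5 FPKM, with the common sum, without the micropylar endosperm, and all scalings of the lists were chosen only after the results were seen. No paired analysis was possible because the deposited table holds 1 column per group, and the omission of replicates, library weights, other variance models, set tests and permutation tests were not run for the same reason. The number of genes at least 2-fold apart stayed within 1.5 times for all 15 comparisons with a pseudocount of 0.1 (10879 to 21893), no filter (11516 to 22085), a filter of 5 FPKM (9040 to 18095), quantile normalisation (9667 to 19922), the common median (10575 to 19647) and the common sum (11200 to 22873), and for the 8 comparisons that average over the micropylar endosperm with other columns, when it was left out (11432 to 19955). Without the floor of 5 FPKM it was 21616 for chalazal against peripheral endosperm, 32741 for chalazal against micropylar endosperm, 35018 for micropylar against peripheral endosperm, 30073 for chalazal proliferating tissue against chalazal endosperm, 23094 for chalazal proliferating tissue against inner seed coat and 22864 for inner against outer seed coat, because genes near 0 then pass. Quantile normalisation moved the median of all genes by -0.24 log2 for the inner seed coat to 0.28 for the micropylar endosperm.

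At 5 FPKM, genes detected were 22632 in the embryo proper, 20803 in the micropylar endosperm, 21194 in the peripheral endosperm, 19924 in the chalazal endosperm, 20915 in the chalazal proliferating tissue, 23465 in the inner seed coat, 21756 in the outer seed coat and 22689 in the whole seed. The A share without the 100 genes of highest mean value, and then among detected genes, was 47.3% and 48.8% in the embryo proper, 47.6% and 48.8% in the micropylar endosperm, 47.1% and 46.6% in the peripheral endosperm, 49.9% and 47.6% in the chalazal endosperm, 47.0% and 46.5% in the chalazal proliferating tissue, 48.1% and 46.7% in the inner seed coat, 47.8% and 47.5% in the outer seed coat, and 49.0% and 48.3% in the whole seed. The low A share of the micropylar endosperm thus rests on those 100 genes. Genes of rRNA and organelles were kept in these shares. Among them, the chloroplast ribosomal RNA gene BnaC09g30110D counted as C, at 172243 FPKM in the micropylar endosperm. How far such genes set the low share was not computed.

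Of 225 list medians, 128 lay outside the central 95% of random lists, 133 under quantile normalisation, 119 with the common median and 129 with the common sum. Random lists drew genes singly, while copies of 1 locus in a list mostly moved together. The 95% range is therefore likely too narrow, and these counts are a description. The sign of the median turned in 2, 3 and 7 of those 128 under the same scalings, and none passed from 1 tail to the other. The majority of copies higher or lower turned in 4, 8 and 21 of the 225. Of 945 named genes in a comparison, 925, 933 and 922 kept their call under these scalings, and none turned. They were picked for large differences in the same values, which makes a turn unlikely. With the filter of 5 FPKM in 2 columns, 819 kept their call and 126 were not compared. The micropylar endosperm could be left out only in the 8 comparisons that average it with other columns. Named genes of the other comparisons were not evaluated in this way. With that column left out, 475 named genes kept their call, 28 kept their direction but fell short of the rule, and 1 turned. This was the PP2-A1 copy BnaA01g34970D, from 1.35 to -0.33 log2 in filial against maternal compartments, since that column alone carried it. The majority of copies higher or lower turned in 7 of the 120 list results that could be compared.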

Other observations

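Of the tests in this part, those of sampling and of slopes for the copy ratio, of the storage and phloem transcripts and of the whole seed column were chosen only after the result was seen; the correlation for a shared copy choice and the regrouping of compartments were set before. Defensin-like genes, here with the low-molecular-weight cysteine-rich ones, and S1-family genes were mostly highest in the endosperm. Of 164 such defensin-like genes that reached 5 FPKM, 78 were highest in the chalazal, 51 in the peripheral and 34 in the micropylar endosperm, and none in the embryo proper or a seed coat layer with FPKM as deposited. Under the common sum these were 71, 51 and 40. Their FPKM summed to 291305 in the chalazal endosperm, 172526 in the peripheral and 57988 in the micropylar endosperm, against at most 1986 in a maternal compartment and 886 in the embryo proper. S1-family genes, 57 in number, were highest in the peripheral endosperm for 26, in the chalazal for 18 and in the micropylar for 10. F-box genes were highest in the chalazal endosperm for 141 of 455, and for 94 with the common sum. Pentatricopeptide repeat genes, which act in organelle RNA processing, were highest in the embryo proper for 80 of 175. These families were chosen after their values were seen.

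Copies of 1 Arabidopsis locus often went to the same compartment. Among 3839 loci with at least 2 copies that each stood 2-fold above every other compartment somewhere, 1966 had all such copies in 1 compartment and 1873 (48.8%) in different ones, against a mean of 3399 and a lowest of 3335 in 1000 shuffles of compartments among copies. The MINI3 locus was an example of the latter, with BnaAnng25430D at 360 FPKM in the micropylar endosperm and BnaA08g29320D at 99 in the peripheral endosperm. The most frequent pairs of compartments included the micropylar endosperm, with 347 loci for the embryo proper and 231 for the outer seed coat. Pairs without it had at most 143. Scatter of copies in that column, described below, may thus add to the loci with copies in different compartments. Reads that match several copies would have the opposite effect. How such reads were assigned is not stated, and the shuffles do not allow for them.

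The grouping into filial and maternal compartments was compared with the other ways of splitting the 7 compartments into 4 and 3. Of 35 splits, 2 gave as many genes at least 2-fold apart as the real one, itself included: 14641 for filial against maternal and 14732 for the highest other split, which put the embryo proper with the 3 maternal compartments. Chance cannot be excluded on this count.

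In the micropylar endosperm, A and C copies of a pair diverged more than elsewhere, with a median departure of 1.61 log2. The embryo proper came next at 0.92, and the peripheral endosperm was at 0.47. A choice of copy shared by the endosperm regions cannot be told apart from a private one: the correlation with the peripheral endosperm was 0.215 of that of the chalazal endosperm across 1001 pairs, but noise lowers a correlation, and the ratio of slopes, 0.450, ran from -0.0476 to 0.899 on resampling of pairs (95%). Sampling of few molecules from a small dissected tissue may contribute, since the departure at 50 FPKM or more was 0.509 of that at 5 to 10 FPKM. It stays open why it was still 1.02 log2 at 50 FPKM or more, against 0.85 in the embryo proper and 0.43 in the peripheral endosperm. A difference of the tissue itself was not tested apart from this.

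Storage protein and oleosin transcripts were highest in the micropylar endosperm for 28 of 30 copies, a subset chosen after its values were seen, against 3 of the 17 other copies of the reserve list. Sampling of few molecules, storage transcripts only, is argued against where it hits loci independently: with copies summed, 10 of 14 loci of the reserve list fixed before were highest there, a number reached in 0 of 10000 random lists matched on expression (at most 9 loci). Carry-over of cells like those of the embryo proper is argued against as the main source of these transcripts. Embryo regulators, which such cells would bring too, had a median ratio of 0.111 to the embryo proper over 39 copies. The storage and oleosin copies had 15.6. Some carry-over is left open: embryo regulators gave 12 higher, 4 lower and 35 neither in this column against the other 6 compartments. For the phloem transcripts, carry-over of vascular tissue cannot be told apart from expression in the endosperm. Of the 5 vascular loci with a copy compared, 3 reached 5 FPKM there: PP2-A1, SUC2 and the xylem marker XCP1. The 6 loci set for carry-over could not be reached. Early expression of storage genes in the cells around the embryo is a hypothesis that these values leave open.

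Genes of rRNA and organelles were nearly missing from the whole seed column. Of 22 such genes at 100 FPKM or more in every compartment, 17 (77.3%) were listed at 0 in the whole seed, against 3 of 170 other genes at that level. They were thus at 0 in the whole seed 43.8 times as often as the others. This ratio restates the pattern for genes chosen as high in every compartment. It therefore does not test a low level in the tissues of the intact seed. A whole seed column made without these transcripts, by another library method or by filtering, may be the cause but the share fell short of the 80% set for it, so it cannot be told apart from a loss of some genes.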
